A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

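Ribosome footprints, the RNA fragments that 80S ribosomes protected from RNase I, were sequenced from 20 libraries of Saccharomyces cerevisiae in 10 groups of 2. The series also names RNA sequencing, which is not analysed here, so footprint counts were not divided by transcript abundance and no translational efficiency was computed. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples.

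Per the submitters' processing notes, reads were aligned to R64 with STAR 2.7.2b and counted with RSEM 1.2.31. The deposited unit is RSEM expected counts per gene feature, not scaled for depth, and each table lists 7127 features. The strand setting used for counting is not given in the sources used here. The expected counts deposited by the authors were rounded to whole numbers for the tests, and totals and shares were computed on the unrounded values. A table of RefSeq genes matched 6047 of the features by locus tag, and 6691 features were kept as protein-coding. Of the open reading frame (ORF) features, 683 were not in that table. The coordinates of such features are not used here.

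Because most counts lay on ORF features outside the RefSeq table, the gene opposite each was sought. Overlap with a gene on the other strand was read from coordinates where the feature had them, with a minimum of 30 nt. Otherwise the gene was inferred from the order and strand in the systematic names. A single opposite neighbour was found for 250 features, several candidates for 357 and none for 46. For 21 features the overlap was written by hand from general knowledge of the yeast genome. The remaining features, whose names give no chromosome arm or strand, had no gene assigned. In the text a feature keeps its deposited name, with the opposite gene after it, and candidates are given as "between X and Y" where they could not be resolved. This assignment, and every test that uses it, was chosen after the counts were seen.

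Differences were tested with edgeR 4.0.16 (quasi-likelihood fit with a robust prior, in R 4.3.3) on all 20 libraries with 1 mean per group, which left 10 residual degrees of freedom. Library sizes were scaled with TMM factors, which ranged from 0.364 to 3.34. Features were filtered with filterByExpr at a minimum count of 10, which kept 1399 features, 437 of them not in RefSeq. The common biological coefficient of variation was 0.11. P-values were adjusted by the Benjamini-Hochberg method and a feature was called at an adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Mean values per group are given as CPM, counts per 1e+06 of the scaled library size, or as percent of the library total, with the standard deviation (SD).

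The comparisons were MTF minus MTFi, EcFMT minus R42L within each of 4 strains, the mean of those 4 differences, an F test that the 4 are equal, each pairwise difference between the within-strain differences, and each strain minus the mean of the other 3 within R42L. These comparisons, their tests, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule names 5 target genes in every group. It also names up to 8 features per direction with the largest log2 change among those with an adjusted p under 0.05, an average log2 CPM of at least 4 and replicate values that do not overlap between the groups. The condition on overlap was not applied to the mean over 4 strains. Up to 4 members of smallest adjusted p were named for lists that passed, and in any case for initiation factors, ribosome-associated quality control, Gcn4 targets, N-terminal processing, chaperones and ribosomal proteins. Where fewer than 5 features passed, the 3 of smallest p in each direction were named as not passing. Of the features the rule names, 1 is not reported here.

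Of 33 gene lists fixed before the data were examined, those with at least 5 testable members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, all deposited features, a fit of only the libraries compared, a replicate block, EcFMT in place of R42L libraries for strains, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. Library totals without scaling factors, a fit of only the features not in RefSeq with scaling factors from them, a crossed replicate block and the mean without RLI1_depl were added after seeing the data. The fit of features not in RefSeq changes the tested features and the scaling together. Splits of the 16 libraries of the 4 strains that reassign EcFMT and R42L within strains were drawn 100 times, the real one included.

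Library totals ranged from 58090 to 505676 expected counts. The test was also tested on simulated data in which, per within-strain comparison, 100 features were changed 2-fold and 100 others 4-fold. Increases and decreases were equal in number, so the simulation does not cover errors that scaling may cause. Among features with a mean of at least 50 counts, 85.7 to 94.7% of 2-fold changes and 100% of 4-fold changes were recovered, with 0 to 2 false calls per comparison. Over all tested features, 20 to 28% of 2-fold and 29 to 59% of 4-fold changes were recovered. Intervals rest on the SE of the edgeR fit, which includes its fitted spread between libraries. Floors cover counting error only. For a count of 0 the floor was 3 counts over the group, on shares of library totals, and folds against such a group are given as at least that size. Figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.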

Results

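Ribosome profiling was carried out in budding yeast that the labels give as fmt1 cells and that expressed the methionyl-tRNA formyltransferase of E. coli (EcFMT) or its R42L form. The enzyme puts a formyl group on the methionine of initiator tRNA. The study addressed how formylation bears on translation. Groups labelled MTFi and MTF, whose names the labels do not spell out, held 2 libraries each. The other 16 libraries came from 4 strains, each with EcFMT and with R42L in 2 replicates. The strain label arf1D names Arf1, a small GTPase of Golgi transport. The label hrc1D resembles HCR1, which encodes the initiation factor subunit eIF3j. NIP1_depl names eIF3c and RLI1_depl names the ribosome-recycling ATPase Rli1. Cells grew at 30 °C in synthetic complete medium to an A600 near 0.5.

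Depth differed by strain. Total expected counts per library were 307898 to 492363 in MTFi, 310903 to 365722 in MTF, 405061 to 505676 in arf1D with EcFMT and 386355 to 405448 in arf1D with R42L. They were 271972 to 274712 in hrc1D with EcFMT and 153501 to 171995 with R42L. Totals fell to 141776 to 174629 in NIP1_depl with EcFMT, 116661 to 130424 in NIP1_depl with R42L, 92583 to 123204 in RLI1_depl with EcFMT and 58090 to 104382 in RLI1_depl with R42L.

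Of the 4993355 counts in the 20 libraries, 95.99% lay on ORF features that the RefSeq table does not hold, most of them opposite abundantly translated genes. The pyruvate kinase gene CDC19 (R64 chromosome I, 71786 to 73288) held 2 counts over all libraries, and YAL037C-B, opposite it, held 854552. PGK1 (III, 137746 to 138996) held 28 counts and YCR013C, opposite it, 428148. GPM1 (XI, 163642 to 164385) held 18 counts against 394966 on YKL153W. The ribosomal protein gene RPL28 (VII, 310967 to 311927) held 0 counts against 187250 on YGL102C, and SSA1, an Hsp70 gene, held 0 against 136378 on YAL004W. TDH3, TEF1 and TEF2, which no listed feature opposes, held 0.5 counts each, and ENO2 held 12.5. Over 16 ribosomal protein genes with a resolved opposite feature, the features held 1681697 counts and the genes 14.5. The 111 ribosomal protein genes with no opposing feature held 157.5 counts, 0.0032% of all counts. Of 67 RefSeq ORFs that overlap an opposite-strand gene by at least 50 nt, 30 (44.8%) held at least 100 counts, against 322 of 5896 (5.5%) with no such overlap. Values below are therefore given for features under their deposited names, and a gene named as opposite is the one on whose other strand they lie. Counts under the name of a RefSeq gene are likewise not read as translation of that gene, since abundant genes held almost none under their own names.

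**Figure D1:**
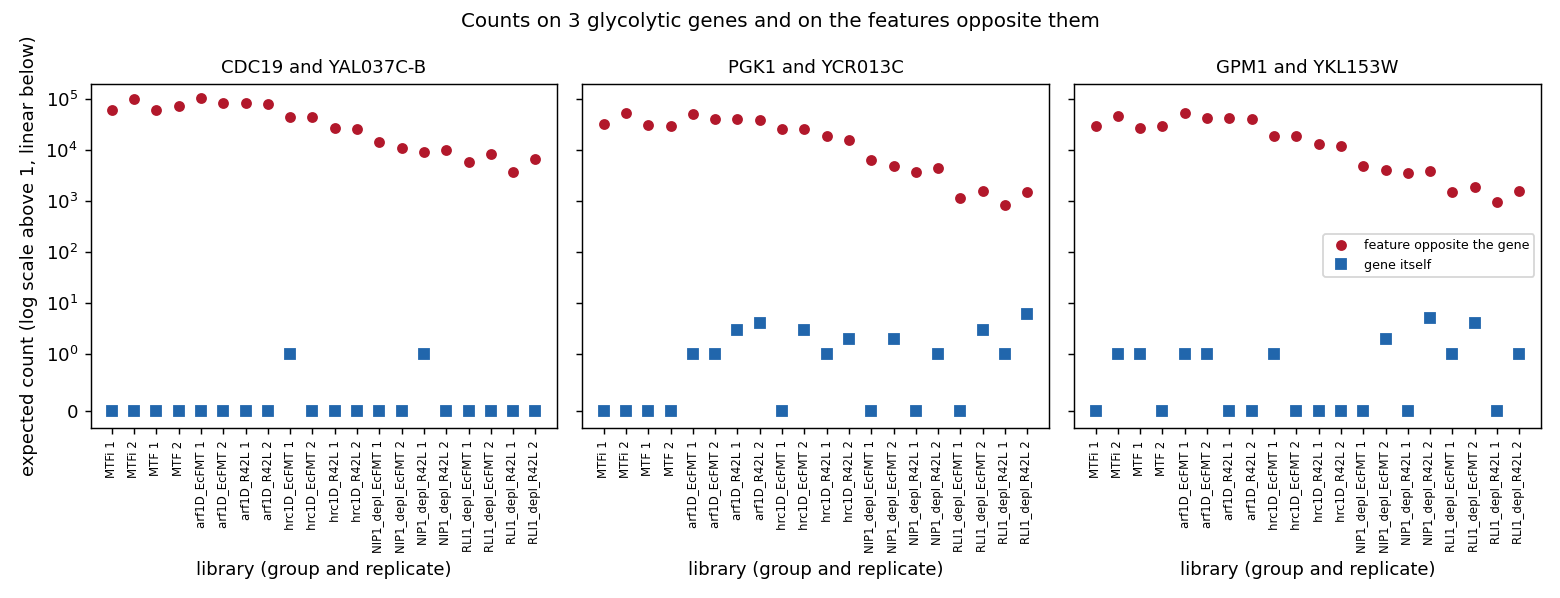
Expected counts (y axis, log scale above 1 and linear below) in each of the 20 libraries (x axis) on 3 glycolytic genes (blue squares) and on the features opposite them (red circles). The features held 854552, 428148 and 394966 counts over all libraries and CDC19, PGK1 and GPM1 held 2, 28 and 18.

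The genes that the strain labels name could not be followed. FMT1 (II, 202056 to 203261) and RLI1 (IV, 626708 to 628534) held 0 counts in every library, which allows up to 6.01e-05% of all counts. ARF1 (IV, 116321 to 116866) held 2.5 counts over the 20 libraries, HCR1 (XII, 538792 to 539589) 3.84 and NIP1 (XIII, 892988 to 895426) 2. The highest group mean among these 5 genes was 1.0 ± 1.41 counts (SD, n = 2) for NIP1 in NIP1_depl with EcFMT. CDC19 held 2 counts too, so these counts say nothing on whether the named genes were deleted or depleted.

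The groups differed in what lay opposite glycolytic genes and on RefSeq ORFs, and less in what lay opposite ribosomal protein genes. Features opposite CDC19, PGK1 and GPM1 took 39.8% ± 0.275 (SD, n = 2) of counts in MTFi and 36.9% ± 1.79 in MTF. They took 41.1% ± 0.123 in arf1D with EcFMT and 32.9% ± 0.0111 in hrc1D with EcFMT, but 14.1% ± 0.521 in NIP1_depl and 9.27% ± 0.187 in RLI1_depl with EcFMT. Features opposite 16 ribosomal protein genes took 31.1% ± 0.194 in arf1D, 33.2% ± 0.209 in hrc1D, 40.4% ± 0.462 in NIP1_depl and 34.2% ± 0.255 in RLI1_depl, all with EcFMT. The ratio of the glycolytic to the ribosomal protein features within a library does not depend on scaling. It was 1.328 ± 0.02 (SD, n = 2) in arf1D, 1.062 ± 0.014 in hrc1D, 0.343 ± 0.005 in NIP1_depl and 0.311 ± 0.006 in RLI1_depl, all with R42L. With EcFMT it was 1.321 ± 0.012, 0.991 ± 0.007, 0.35 ± 0.017 and 0.271 ± 0.008 in the same order, and it was 1.183 ± 0.009 in MTFi and 1.035 ± 0.103 in MTF. RefSeq ORFs with no opposite-strand overlap took 0.468% ± 0.0156 of counts in MTFi, 2.55% ± 0.0231 in hrc1D with EcFMT, 8.19% ± 0.0724 in NIP1_depl with EcFMT, 13.3% ± 0.38 in RLI1_depl with EcFMT and 17.7% ± 0.213 in RLI1_depl with R42L. With both forms of a strain pooled, a choice made after the data were seen, the ratio was 1.325 in arf1D, 1.026 in hrc1D, 0.347 in NIP1_depl and 0.291 in RLI1_depl (n = 4 each). For each of the 6 pairs of strains an exact permutation test over 70 splits gave p = 0.0286, the smallest it can give (Benjamini-Hochberg adjusted p = 0.0286). The ratios of different strains did not overlap, so no other p was possible and the test adds nothing to that separation. It also takes EcFMT and R42L libraries of a strain as replicates. The shares were not tested.

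**Figure D2:**
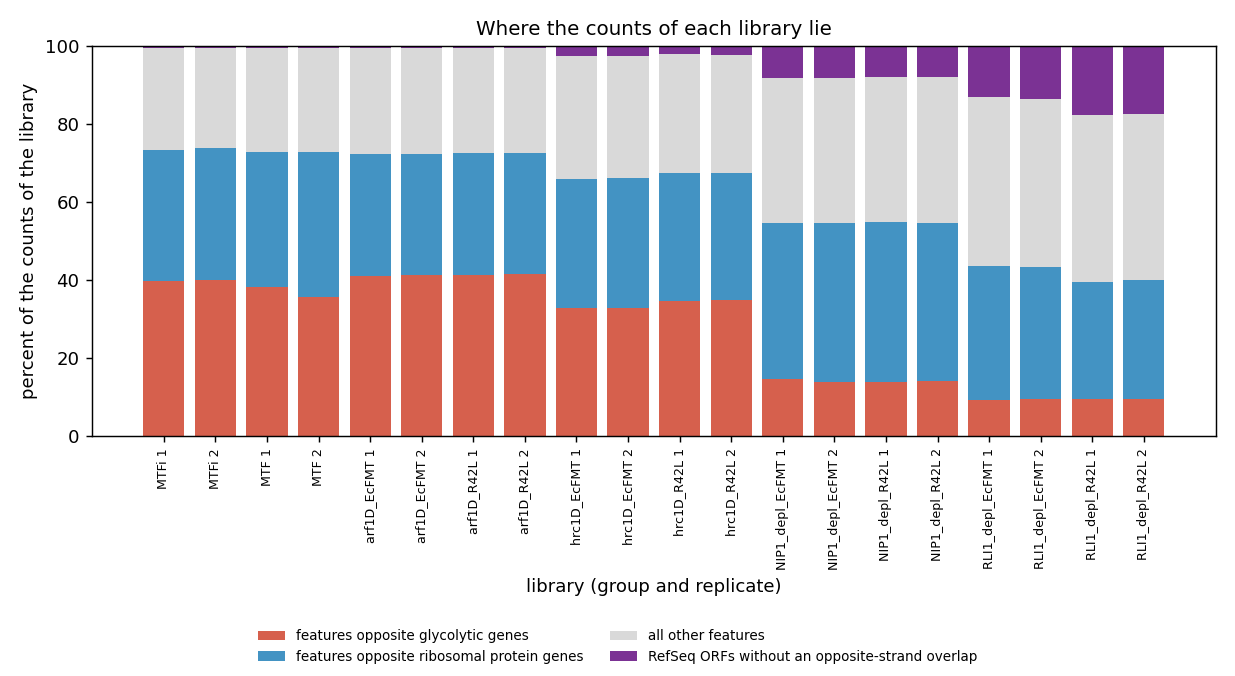
Percent of the counts of each library (y axis) on features opposite glycolytic genes, on features opposite ribosomal protein genes, on RefSeq ORFs without an opposite-strand overlap and on all other features, for the 20 libraries (x axis). The glycolytic part was 41.1% in arf1D with EcFMT and 9.27% in RLI1_depl with EcFMT.

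The comparison of MTF with MTFi asked what the unexplained pair of labels separates. YER067C-A, opposite RGI1 (V, 292066 to 292551), a gene induced in respiratory growth, had the smallest adjusted p and was lower in MTF. It stood at 665 ± 262 CPM in MTF and 2110 ± 523 in MTFi (SD, n = 2 each). Its log2 change was -1.69 (SE 0.19, adjusted p = 3.25e-15, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The SE and p-value rest on a spread fitted over all 10 groups and may understate the spread between the MTF libraries. YKL036C, opposite UGP1 (XI, 369891 to 371390), which makes UDP-glucose, had a log2 change of -1.29 (SE 0.24, adjusted p = 1.98e-05). YER066C-A, between RRT13 and RGI1, had -1.7 (SE 0.24, adjusted p = 7.27e-10). These 3 features kept their call and direction under all 8 alternatives and without each of the 4 libraries in turn. YDL009C, opposite the glutaredoxin gene GRX6, fell by 1.58 on the log2 scale, YJL015C, between TPH3 and CCT3, by 2.25 and YPL185W, between UIP4 and MRN1, by 2.1. YGL149W held 1 count in MTF and 21 in MTFi, and YMR151W, opposite IMP1, held 1 and 17.

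Higher in MTF was SLM6, opposite REI1 (II, 739841 to 741022), a factor of 60S subunit maturation, at a log2 change of 0.97 (SE 0.2, adjusted p = 0.000425, edgeR). Its call ended without MTFi replicate 1, where the log2 change was 0.65. FYV5, opposite ADF1, changed by 0.73, and its call ended without MTFi replicate 1 (0.55), MTF replicate 1 and MTF replicate 2. YGR160W, between NSR1 and RTS3 among other candidates, changed by 0.5 and lost its call without MTFi replicate 1 (0.34) or MTF replicate 2. YJR071W, between LIA1 and NPA3, changed by 0.55 and lost its call without MTFi replicate 1 or MTF replicate 2 (0.24). Of the lower features, YDL009C kept its call only without MTFi replicate 2, YJL015C lost it without MTFi replicate 2 or MTF replicate 1 (-1.64), and YPL185W lost it without MTFi replicate 2 or MTF replicate 2 (-1.27). YGL149W and YMR151W lost theirs without MTFi replicate 2, MTF replicate 1 or MTF replicate 2.

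Of 1399 features, 24 passed at an adjusted p under 0.05, 4 higher and 20 lower. The split depended on scaling, with 33 higher and 12 lower under RLE, 20 and 19 with library totals, and 22 and 6 in DESeq2. A fit of only the 437 features not in RefSeq, which changes the tested features and the scaling together, called 19 higher and 16 lower. RLE moved the median log2 change of all features by 0.2, and in the fit of features not in RefSeq it moved by 0.12. Without MTFi replicate 1 the test called 38 features, all lower, and without MTFi replicate 2 it called 22, 15 higher and 7 lower. Without MTF replicate 1 it called 6 higher and 10 lower, and without MTF replicate 2 it called 2 and 13. The MTF libraries differed from each other by a chi-square per degree of freedom of 8.59, against 1.53 in MTFi. Against the 2 MTFi libraries it was 8.109 and 8.585 for MTF replicate 1 and 11.211 and 12.857 for MTF replicate 2. By this measure MTF replicate 1 lay no closer to MTF replicate 2 than to MTFi. Since the fit shares its spread over all 10 groups, p-values of every comparison that uses MTF may be too small. Among the named lists, YPR044C, opposite RPL43A, stood at 0.32 (SE 0.11, adjusted p = 0.17) and passed under RLE, library totals, the fit of features not in RefSeq, DESeq2 and a fit of the 4 libraries, and without MTFi replicate 2 (0.53). YLR339C, opposite RPP0, at -0.18, YLR076C, opposite RPL10, at -0.14, and YPL250W-A, opposite RPL36B, at -0.22 passed only without MTFi replicate 1 among the left-out libraries. Not called were YOR277C, opposite the eIF4E-binding gene CAF20 (0.15), YPL238C, opposite the eIF2 beta gene SUI3 (-0.08), YGL214W, opposite SKI8 (0.11), YNL103W-A, opposite LEU4 (-0.46), YER090C-A, opposite TRP2 (0.02), YPR050C, opposite the N-acetyltransferase gene MAK3 (-0.13), YMR135W-A, opposite GID8 (-0.18), YAL004W, opposite SSA1 (-0.07), YGL074C, opposite HSF1 (0.18), and YLR217W, opposite CPR6 (-0.01). Over 14 features opposite ribosomal protein genes none was called, nor adjusted over the list alone, with a median log2 change of 0 under TMM and 0.21, 0.09 and 0.12 under RLE, library totals and the fit of features not in RefSeq, which called 5, 2 and 3 of them higher. The camera test gave adjusted p = 0.525 (adjusted p = 0.814 with an estimated correlation), but 0.00349 (0.0924) under RLE, 0.0625 (0.197) with library totals and 0.0204 (0.0418) in the fit of features not in RefSeq. Over 6 features opposite ribosome biogenesis genes the median was 0.21, with 1 called higher (2 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 0.0763 (adjusted p = 0.541 with an estimated correlation), against 0.0028 (0.0924) under RLE, 0.00434 (0.173) with library totals and 0.0875 (0.282) in the fit of features not in RefSeq.

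The 4 comparisons of EcFMT with R42L asked what EcFMT changes relative to its R42L form in each strain. In arf1D no feature passed. Arf1 recruits vesicle coats at the Golgi. ISF1 held 9 counts with EcFMT and 0 with R42L, and YDR250C, opposite PAM1, held 8 and 0. MRK1, a kinase gene, had a log2 change of 2.16 and adjusted p = 1. Lower with EcFMT were MET28 (0 counts against 5), SNN1 (0 against 4) and SCS22 (1 against 7), none of which passed. YPL238C, opposite SUI3, stood at -0.11 and YOR277C, opposite CAF20, at 0.11. With edgeR, 0 of 1399 features passed, with 39 at an unadjusted p under 0.05, and DESeq2 called 0. Of 252 features with a mean of at least 50 counts, 195 had a 95% interval within 1.5-fold. The 14 features opposite ribosomal protein genes had a median of -0.01 with 0 called, nor any adjusted over the list alone (camera adjusted p = 0.89, adjusted p = 0.959 with an estimated correlation). Their mean was positive where the median and the test were negative. The 6 opposite ribosome biogenesis genes had a median of -0.02. Without arf1D_EcFMT replicate 2 the test called 1 feature.

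In the hrc1D strain no feature passed either. Of the features with the smallest p, IRC8 had a log2 change of 2.53 (SE 0.7, adjusted p = 0.359, edgeR). MET10, a sulfite reductase gene, held 16 counts with EcFMT and 0 with R42L. YHR137C-A, opposite the aromatic aminotransferase gene ARO9 (VIII, 375709 to 377250), stood at 0.68 (SE 0.24, adjusted p = 0.828). Lower with EcFMT were YGR114C, between DAM1 and SPT6, at -1.34 (SE 0.38, adjusted p = 0.359), YPL182C at -0.77 (SE 0.26, adjusted p = 0.754), and MEP1, an ammonium permease gene, with 0 counts against 7. YLR339C, opposite RPP0, stood at -0.18. Testing with edgeR called 0 of 1399 features, with 57 at an unadjusted p under 0.05, and DESeq2 called 0. Of 228 features with a mean of at least 50 counts, 138 had a 95% interval within 1.5-fold. The median opposite ribosomal protein genes was 0.01 with 0 called, nor any adjusted over the list alone (camera adjusted p = 0.896, adjusted p = 0.961 with an estimated correlation), and opposite ribosome biogenesis genes it was -0.11. For the ribosomal protein features the median and mean were positive and the test direction negative. Without hrc1D_R42L replicate 2 the test called 3 features, among them YGR114C at -2.09.

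In the NIP1_depl strain, which is named for the eIF3 subunit that contacts initiation factors on the 40S subunit, again no feature was called between EcFMT and R42L. MNN4, a mannosylation gene, stood at 0.95 (SE 0.31, adjusted p = 1, edgeR), YBR056C-B, between MRX18 and MNC1, at 0.85 (SE 0.32) and YAL064W-B at 1.56. SAS2 stood at -2.35 (SE 0.81), YKL083W, opposite RRP14, at -0.67 (SE 0.28), and APS2 held 0 counts against 5. YOR277C, opposite CAF20, stood at 0.26 and YPL238C, opposite SUI3, at -0.09. The edgeR test called 0 of 1399 features, with 42 at an unadjusted p under 0.05, and DESeq2 called 0. Of 241 features with a mean of at least 50 counts, 140 had a 95% interval within 1.5-fold. The median opposite ribosomal protein genes was 0.09 with 0 called, nor any adjusted over the list alone (camera adjusted p = 0.501, adjusted p = 0.804 with an estimated correlation), and opposite ribosome biogenesis genes it was -0.12 (camera adjusted p = 0.18, adjusted p = 0.726 with an estimated correlation). Without NIP1_depl_R42L replicate 2 the test called 1 feature.

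In the RLI1_depl strain, features opposite several ribosomal protein genes were called higher with EcFMT and features opposite RGI1 and MET2 lower. Abundant features as a whole were higher under TMM, with a median log2 change of 0.31 over the 231 with a mean of at least 50 counts, and the ribosomal protein list did not pass the camera test with an estimated correlation there (adjusted p = 0.122). YGL102C, opposite RPL28, stood at 11940 ± 554 CPM with EcFMT and 8142 ± 361 with R42L (SD, n = 2 each), a log2 change of 0.55 (SE 0.11, adjusted p = 0.000198, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). YLL044W, opposite RPL8B (XII, 47859 to 48629), changed by 0.54 (SE 0.11, adjusted p = 0.000281). Both kept their call without each of the 4 libraries in turn and under 7 of 8 alternatives. YLR339C, opposite the stalk protein gene RPP0, changed by 0.56 and lost its call without RLI1_depl_R42L replicate 1 (0.5). YGL123C-A, opposite RPS2, changed by 0.6 and lost it without RLI1_depl_EcFMT replicate 1 (0.45). Of the 14 features opposite ribosomal protein genes, 10 were called higher and 0 lower (12 higher adjusted over the list alone), and their median log2 change of 0.46 stayed positive under RLE (0.32, 8 called), the fit of features not in RefSeq (0.18, 5 called) and library totals (0.15, 4 called). The camera test gave adjusted p = 1.79e-05 (adjusted p = 0.122 with an estimated correlation), and 0.00012 (0.0291) under RLE, 0.0042 (0.0634) with library totals and 0.00273 (0.0145) in the fit of features not in RefSeq. Without RLI1_depl_EcFMT replicate 1, RLI1_depl_EcFMT replicate 2, RLI1_depl_R42L replicate 1 or RLI1_depl_R42L replicate 2 the list kept 5, 6, 3 and 5 calls, at medians of 0.44, 0.44, 0.47 and 0.45.

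**Figure D3:**
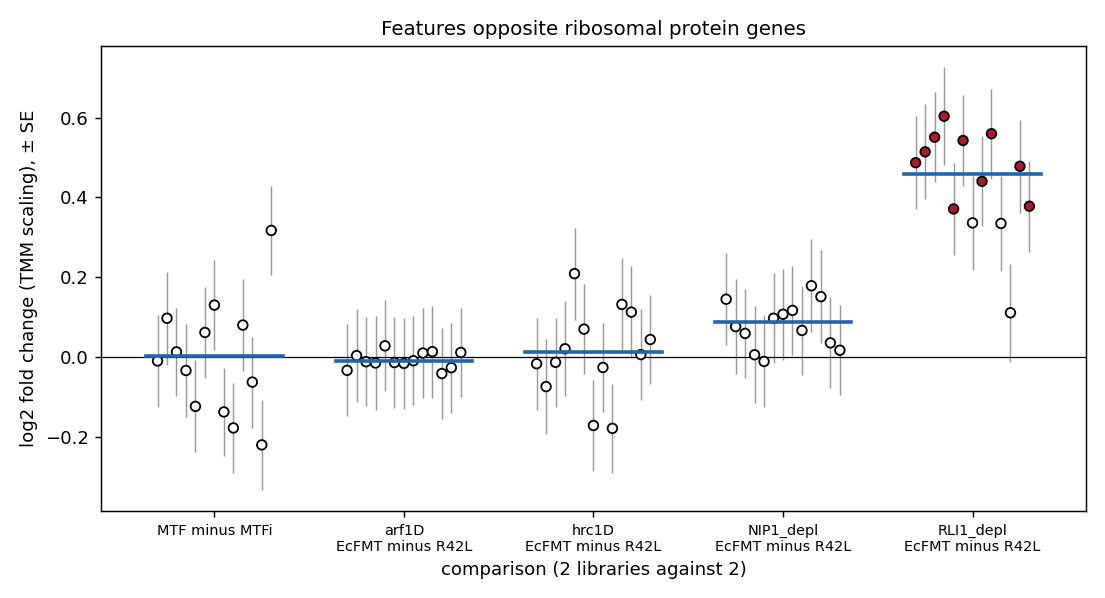
Log2 fold change with SE (y axis, TMM scaling) of 13 features opposite ribosomal protein genes in each of 5 comparisons of 2 libraries against 2 (x axis), with calls at an adjusted p under 0.05 in red and the median of all 14 features as a blue line. YNL303W, the feature with the lowest average counts, is not drawn. It held 0 to 3 counts outside RLI1_depl, and in RLI1_depl 17.1 and 26.9 with EcFMT and 21.9 and 26.2 with R42L. Counts so far below those of the other 13 features put its placement opposite a ribosomal protein gene in doubt, though it was kept in the list. The median was 0.46 in RLI1_depl and stayed positive there under RLE (0.32), the fit of features not in RefSeq (0.18) and library totals (0.15), whereas in MTF minus MTFi it moved from 0 to 0.21 under RLE.

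Of 6 features opposite ribosome biogenesis genes, 4 were called higher in RLI1_depl under TMM, 1 under RLE and 0 with library totals or in the fit of features not in RefSeq, and the list did not pass with an estimated correlation under TMM (adjusted p = 0.1). YLR198C, opposite NOP56 (XII, 546097 to 547611), a core protein of box C/D snoRNPs, changed by 0.9 (SE 0.23, adjusted p = 0.00415, edgeR) and lost its call without RLI1_depl_EcFMT replicate 2 or RLI1_depl_R42L replicate 1 (0.78). YPR142C, opposite RRP15, changed by 0.72, YNL174W, opposite NOP13, by 0.67 and YMR290W-A, opposite HAS1, by 0.7, and each lost its call without at least 3 of the 4 libraries, with RLI1_depl_EcFMT replicate 1 and RLI1_depl_R42L replicate 1 among them every time. Adjusted over the list alone 5 were called, at a median of 0.7 that was 0.55 under RLE, 0.39 with library totals and 0.41 in the fit of features not in RefSeq. The camera test gave adjusted p = 7.81e-05 (adjusted p = 0.1 with an estimated correlation), and 0.00012 (0.0291) under RLE, 0.00152 (0.0634) with library totals and 0.00273 (0.0732) in the fit of features not in RefSeq. Without RLI1_depl_EcFMT replicate 1, RLI1_depl_EcFMT replicate 2, RLI1_depl_R42L replicate 1 and RLI1_depl_R42L replicate 2 in turn, 1, 1, 0 and 2 of them were called. Among initiation factors, YPL238C, opposite SUI3 (XVI, 100496 to 101353), changed by 0.73 (SE 0.15, adjusted p = 0.000263) and lost its call without RLI1_depl_R42L replicate 1 (0.6). YOR277C, opposite CAF20, changed by 0.65 (SE 0.19, adjusted p = 0.0274) and lost its call without any 1 of the 4 libraries (0.49 without RLI1_depl_R42L replicate 2). YNL103W-A, opposite the Gcn4 target LEU4, changed by 0.62 and kept its call only without RLI1_depl_EcFMT replicate 2.

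Other features higher with EcFMT in RLI1_depl were YAL042C-A, between ERV46 and CDC24, at 0.9 (SE 0.19, adjusted p = 0.000281, edgeR), which lost its call without RLI1_depl_R42L replicate 1 (0.74), and YBR056C-B, between MRX18 and MNC1, at 0.75 (SE 0.15, adjusted p = 0.000144), which kept it without each library. YMR119W-A, between SHH3 and ADE17, at 1.96, YBR174C, opposite SWD3, at 0.81 and FYV5, opposite ADF1, at 0.76 lost their calls without any 1 of the 4 libraries. YBL100W-A held 16 counts with EcFMT and 0 with R42L, at least 4.02-fold higher, and passed only without RLI1_depl_EcFMT replicate 2 among the left-out libraries. YOR343W-A held 38 and 2 counts and lost its call without RLI1_depl_EcFMT replicate 1 or RLI1_depl_R42L replicate 2. Both features had fractional counts with EcFMT, 7.5 and 7.9 on YBL100W-A and 21.1 and 16.8 on YOR343W-A. Reads shared with other features may thus have been split between them, which the floor does not cover. Lower were YER067C-A, opposite RGI1, at -2.23 (SE 0.39, adjusted p = 5.35e-06), YNL276C, opposite MET2 (XIV, 117349 to 118809), at -1.69 (SE 0.33, adjusted p = 0.000105), APM3 at -1.53 (SE 0.25, adjusted p = 2.07e-06) and YNL057W, opposite YNL058C, at -0.89 (SE 0.18, adjusted p = 0.000198), and these 4 kept their calls without each library in turn. YER066C-A changed by -1.29 and lost its call without RLI1_depl_EcFMT replicate 2 (-1.13), and SSH1, at -1.29, and YLR120W-A, between YPS1 and YPS3, at -1.96 lost theirs without any 1 of the 4. YIR017W-A, between MET28 and YIR018C-A, changed by -1 (SE 0.22, adjusted p = 0.000461). Not called were YER090C-A, opposite TRP2 (0.86, adjusted p = 0.414), YAL004W, opposite SSA1 (0.29, adjusted p = 0.203), YGL214W, opposite SKI8 (0.24), YPR050C, opposite MAK3 (0.18), YMR135W-A, opposite GID8 (0.05), YGL074C, opposite HSF1 (0.27), and YLR217W, opposite CPR6 (0.15).

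In RLI1_depl 48 of 1399 features passed, 39 higher and 9 lower. The split moved to 23 and 14 under RLE, 11 and 28 with library totals, and 30 and 3 in DESeq2, and to 12 and 15 in the fit of only the 437 features not in RefSeq. The median log2 change of all features shifted by -0.14 under RLE, -0.31 with library totals and -0.28 in the fit of features not in RefSeq. The named members YER067C-A and YGL102C kept their direction under each. Without RLI1_depl_EcFMT replicate 1, RLI1_depl_EcFMT replicate 2, RLI1_depl_R42L replicate 1 and RLI1_depl_R42L replicate 2 the test called 20, 29, 16 and 19 features.

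The mean of the 4 within-strain differences asked what EcFMT changed in common. YBR056C-B, between MRX18 and MNC1, rose by a log2 of 0.47 (SE 0.11, adjusted p = 0.0146, edgeR). YCR087W, opposite YCR087C-A (III, 264006 to 264467), rose by 0.36 (SE 0.08, adjusted p = 0.0146), YAL042C-A, between ERV46 and CDC24, by 0.35 (SE 0.09, adjusted p = 0.0288) and YHR137C-A, opposite ARO9, by 0.34 (SE 0.09, adjusted p = 0.0339). YBL100W-A passed too (adjusted p = 0.0288) with 0 to 16 counts per library, many of them fractional, so a split of shared reads between features may bear on its call. The test called these 5 features, all higher, with 0 called once RLI1_depl was left out of the mean. YBR056C-B lost its call without NIP1_depl_R42L replicate 1 (0.41) or 4 further libraries, arf1D_R42L replicate 1, hrc1D_EcFMT replicate 2, hrc1D_R42L replicate 1 and NIP1_depl_EcFMT replicate 1. YCR087W kept its call without 7 of the 16 libraries in turn, YAL042C-A and YBL100W-A without 4 and YHR137C-A without 1, all with the same sign. The test called 0 features without arf1D_R42L replicate 1, hrc1D_EcFMT replicate 2 or hrc1D_R42L replicate 1, and 1 without arf1D_R42L replicate 2, NIP1_depl_R42L replicate 2 or RLI1_depl_EcFMT replicate 1. It called 2 without arf1D_EcFMT replicate 1, NIP1_depl_EcFMT replicate 1, NIP1_depl_R42L replicate 1 or RLI1_depl_R42L replicate 2, and 3 without hrc1D_EcFMT replicate 1, NIP1_depl_EcFMT replicate 2, RLI1_depl_EcFMT replicate 2 or RLI1_depl_R42L replicate 1. Over the 14 features opposite ribosomal protein genes 0 were called (9 higher adjusted over the list alone) at a median of 0.14 (0.08, 0.05 and 0.04 under RLE, library totals and the fit of features not in RefSeq), with camera adjusted p = 0.00439 (adjusted p = 0.415 with an estimated correlation), and 0.0303, 0.126 and 0.0551 under the same 3 alternatives (0.306, 0.396 and 0.0819 with an estimated correlation). The list members with the smallest p were YLL044W, opposite RPL8B (0.17, adjusted p = 0.184), and YAL004W, opposite SSA1 (0.18, adjusted p = 0.184), neither called.

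The F test that EcFMT acted alike in the 4 strains called 10 features. YER067C-A, opposite RGI1, had the smallest adjusted p, 0.000124 (edgeR). YLR339C, opposite RPP0, YPL238C, opposite SUI3, YER066C-A, YGR160W and APM3 had 0.0108, YEL034C-A, opposite the eIF5A gene HYP2, had 0.0143, and YDL023C, opposite the glycerol gene GPD1, YNL276C, opposite MET2, and YIR017W-A had 0.0343. The calls rested on RLI1_depl, since 0 remained without RLI1_depl_EcFMT replicate 1, 2 without RLI1_depl_EcFMT replicate 2 and 1 without RLI1_depl_R42L replicate 1 or RLI1_depl_R42L replicate 2. Without hrc1D_R42L replicate 2 there were 16 calls, without hrc1D_EcFMT replicate 2 there were 5, and without hrc1D_R42L replicate 1, arf1D_R42L replicate 1 or arf1D_R42L replicate 2 there were 6.

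Correlations of effects were taken across 246 abundant features, which are not independent replicates, and shared calls and their chance counts over all 1399 tested features. The chance counts take each tested feature as equally likely to be called, and are therefore too low. Among the calls, 19 of 24 in MTF minus MTFi and 42 of 48 in RLI1_depl were not in RefSeq, as were 437 of the tested features. MTF minus MTFi and RLI1_depl EcFMT minus R42L had Pearson r = 0.337 and Spearman rho = 0.356 and shared 2 called-higher features, FYV5 and YGR160W, where chance gives 0.112, and 4 called-lower features, YER066C-A, YER067C-A, YNL276C and YOR121C, where chance gives 0.129. YDL023C, opposite GPD1, was called in opposite directions, at -0.64 in MTF minus MTFi and 0.43 in RLI1_depl. YOR121C lies opposite the glycerol dehydrogenase gene GCY1. MTF minus MTFi and arf1D had r = 0.597, which was -0.083 without YIL082W-A.

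Strains were compared within R42L, each against the mean of the other 3, to ask how each differed from the others. No strain without a deletion or depletion label was part of this comparison. A difference may therefore come from the other 3 strains and is not shown to be an effect of the named gene. The camera test sets a list against all tested features, most of them RefSeq ORFs, whose share of counts also differed between strains. With R42L the features opposite ribosomal protein genes took 31.1% of counts in arf1D, 32.7% in hrc1D, 40.7% in NIP1_depl and 30.3% in RLI1_depl. A list higher or lower against all features therefore need not have changed its own share in that direction. Values depended on scaling. Library totals shifted the median log2 change of all features by -2.01 in arf1D, -0.65 in hrc1D, 0.88 in NIP1_depl and 1.81 in RLI1_depl, RLE by -0.74, -0.27, 0.37 and 0.64, and the fit of features not in RefSeq by -0.95, -0.31, 0.39 and 0.86.

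The arf1D strain had a larger share of counts opposite glycolytic genes than the other 3 strains, at 41.3% with R42L. The share in MTFi was near it, at 39.8%, so this was not particular to arf1D. YKL153W, opposite GPM1, was higher by a log2 of 3.73 (SE 0.08), between 1.61 and 3.73 over 8 alternatives. YJL026C-A, between RNR2 and RRN7, was higher by 4.53 (SE 0.12, adjusted p = 8.99e-289, edgeR) and YGL014C-A, opposite the RNA-binding protein gene PUF4 (VII, 466141 to 468807), by 4.38 (SE 0.39, adjusted p = 2.24e-28). YER090C-A, opposite the tryptophan gene TRP2, was higher by 4.13 (SE 0.21, adjusted p = 4.07e-87), between 2.02 and 4.13 over 8 alternatives. Several features held 0 counts in arf1D with R42L, namely YGR114C, between DAM1 and SPT6 (at least 94.4-fold lower), CIR2 (at least 55.7-fold), YDR250C, opposite PAM1 (at least 41.7-fold), MSH4 (at least 25.1-fold), SPO11 (at least 24.1-fold) and MEK1 (at least 23.3-fold). These bounds are for R42L only. With EcFMT, arf1D held 6 and 2 counts on YDR250C and 2 and 2 on MEK1. On YGR114C, CIR2, MSH4 and SPO11 it held 0 or 1 per library. In MTFi and MTF, CIR2 and SPO11 held 0 counts in every library, and YGR114C, YDR250C, MSH4 and MEK1 held 0 to 4. Such low counts were thus not particular to arf1D. RefSeq ORFs without an overlap held 0.558% of counts in arf1D with R42L against 2.27, 7.90 and 17.7% in hrc1D, NIP1_depl and RLI1_depl, so the folds of CIR2, MSH4, SPO11 and MEK1 were not shown to be specific to these ORFs. ISF1 was at least 21.9-fold lower and was not called with EcFMT libraries in place of R42L. YIL082W-A was called lower too, but it is 1 of a pair of Ty3 copies with YGR109W-B between which reads were split. Together they held 11 and 13 counts in arf1D and 68 to 240 in the other R42L libraries. In all 517 features passed, 267 higher and 250 lower, against 191 and 513 under RLE, 59 and 901 with library totals and 178 and 360 in DESeq2. YAL004W, opposite SSA1, was higher by 2.6 (0.48 to 2.6 over the alternatives), YOR277C, opposite CAF20, by 3.12 (1.0 to 3.12), and YMR135W-A, opposite GID8, lower at -1.27 (-3.39 to -1.08). The 14 features opposite ribosomal protein genes had a median of 1.91 with 13 called higher, also adjusted over the list alone (camera adjusted p = 5.95e-12, adjusted p = 0.0235 with an estimated correlation), which was 1.14 under RLE and 0.96 in the fit of features not in RefSeq and flipped to -0.21 with library totals. That flip follows the shift of all features by -2.01, and against all features the list stayed higher there (camera adjusted p = 9.98e-05, adjusted p = 0.0259 with an estimated correlation). This test does not separate a rise of the list from the low share of RefSeq ORFs in arf1D.

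The hrc1D strain was higher at YLR349W, opposite the dicarboxylate carrier gene DIC1 (XII, 826977 to 827873), by a log2 of 3.42 (SE 0.15, adjusted p = 1.05e-106, edgeR). It was higher at CHS7 by 4.51 (SE 0.85, adjusted p = 2.46e-06), at YLR286W-A by 3.75 and at ARO10 by 2.91 (SE 0.4, adjusted p = 2.05e-11). PLN1 held 3 counts in the other strains and 17 in hrc1D. YHR137C-A, opposite ARO9, was lower at -3.21 (SE 0.19, adjusted p = 4.59e-63), and ASE1 at -2.52 (SE 0.37, adjusted p = 5.59e-10). With R42L, ASE1 held 6 and 6 counts in hrc1D, 13 and 17 in arf1D, 78 and 66 in NIP1_depl and 86 and 183 in RLI1_depl. RefSeq ORFs without an overlap held 2.27% of counts in hrc1D, against 0.558, 7.90 and 17.65% in those 3 strains. Lower values of ASE1 and CTR1 were thus not shown to be specific to these ORFs or to hrc1D. CTR1 held 0 counts in hrc1D, at least 3.52-fold lower, and its call ended without arf1D_R42L replicate 1, hrc1D_R42L replicate 1 or hrc1D_R42L replicate 2. YAL004W, opposite SSA1, was higher by 1.7 (1.06 to 1.75 over the alternatives) and YOR277C, opposite CAF20, by 1.03 (0.39 to 1.03). There were 238 calls, 193 higher and 45 lower, against 116 and 83 under RLE, 56 and 199 with library totals and 80 and 50 in DESeq2, and 90 and 64 in the fit of only the 437 features not in RefSeq. The test called 137 without hrc1D_R42L replicate 1 and 155 without hrc1D_R42L replicate 2. The median opposite ribosomal protein genes was 0.61 with 12 called higher, also adjusted over the list alone, with 1 lower there (camera adjusted p = 2.84e-06, adjusted p = 0.192 with an estimated correlation), and 0.34 under RLE, 0.3 in the fit of features not in RefSeq and -0.04 with library totals, where the list was still higher against all features (camera adjusted p = 0.0136, adjusted p = 0.145 with an estimated correlation).

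The NIP1_depl strain was higher at HSL1, a cell cycle kinase gene, by a log2 of 5.23 (SE 0.93, adjusted p = 1.88e-07, edgeR), at AIM45 by 5.08 (SE 0.77, adjusted p = 5.55e-10) and at RAX2 by 4.4. In R42L libraries AIM45 held 25 and 28 counts in NIP1_depl, 16 and 33 in RLI1_depl and 0 in arf1D and hrc1D. RAX2 held 13 and 11 in NIP1_depl and 6 and 13 in RLI1_depl, and HSL1 10 and 20 against 2 and 4. RefSeq ORFs without an overlap held 7.90% of counts in NIP1_depl with R42L. In arf1D, hrc1D and RLI1_depl they held 0.558, 2.27 and 17.65%. These folds were thus not shown to be specific to the named ORFs. YBR056C-B, between MRX18 and MNC1, was lower at -4.28 (SE 0.22, adjusted p = 1.47e-77) and YDR524W-C at -3.89. YLR120W-A held 0 counts in NIP1_depl, at least 5.15-fold lower, and YGL014C-A, opposite PUF4, held 1 count against 118. YAL004W, opposite SSA1, was lower at -1.64 (-1.65 to -0.72 over the alternatives), YOR277C, opposite CAF20, at -1.68 (-1.68 to -0.76), and YMR135W-A, opposite GID8, was higher at 1.01 (0.99 to 1.93). YPL238C, opposite SUI3, was at -0.3 under TMM and at 0.09 under RLE. Calls numbered 560, 336 higher and 224 lower, against 479 and 162 under RLE, 674 and 85 with library totals, and 128 and 139 in the fit of only the 437 features not in RefSeq. The median opposite ribosomal protein genes was -0.6 with 12 called lower and 13 adjusted over the list alone (camera adjusted p = 0.000249, adjusted p = 0.227 with an estimated correlation, and 0.0462 to 0.83 under the other scalings), -0.21 under RLE and -0.2 in the fit of features not in RefSeq, and it flipped to 0.32 with library totals, which shifted all features by 0.88 and left the list no different from them (camera adjusted p = 0.83).

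The RLI1_depl strain had the smallest share of counts opposite glycolytic genes among the 4 strains. YCR013C, opposite PGK1, was lower at -4.12 (SE 0.11, adjusted p = 1.09e-268, edgeR) and YKL153W, opposite GPM1, at -3.76 (SE 0.11, adjusted p = 6.5e-234), and over 8 alternatives they reached no higher than -2.28 and -1.92. YJL026C-A was lower at -3.96, YLR349W, opposite DIC1, at -3.61 and YGR160W at -3.28. Several RefSeq ORFs held counts in RLI1_depl with R42L and 0 in the other R42L libraries, namely YBR221W-A (at least 336-fold higher), NOT5 of the Ccr4-Not complex (at least 162-fold), ADF1 (at least 157-fold), CTF8 and MRPS18 (at least 154-fold each) and BRR6 (at least 118-fold). RefSeq ORFs without an overlap as a whole held 17.7% of counts there against 0.558 to 7.90% in the other strains, so these folds were not shown to be specific to the named ORFs. The telomerase gene EST2 held 97 counts against 1 and TSC11 held 81 against 1. MRPS18 was not called in DESeq2. YAL004W, opposite SSA1, was lower at -2.66 (-2.66 to -0.82 over the alternatives), YOR277C, opposite CAF20, at -2.47 (-2.47 to -0.63), and YMR135W-A, opposite GID8, was higher at 0.99 (0.99 to 2.83). Of 1399 features 763 passed, 508 higher and 255 lower, against 743 and 166 under RLE, 1125 and 36 with library totals, and 145 and 116 in the fit of only the 437 features not in RefSeq. The median opposite ribosomal protein genes was -2.07 with 1 called higher and 13 lower, the same adjusted over the list alone (camera adjusted p = 1.61e-11, adjusted p = 0.0358 with an estimated correlation), -1.41 under RLE, -1.21 in the fit of features not in RefSeq and -0.23 with library totals, where the list stayed lower against all features (camera adjusted p = 4.71e-11, adjusted p = 0.00108 with an estimated correlation). The member called higher was YNL303W, whose placement opposite RPS19B is in doubt, with 21.9 and 26.2 counts here and 0 to 2 in the other R42L libraries.

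Opposite ribosome biogenesis genes the strain medians were 2.32 in arf1D (6 of 6 called higher, camera adjusted p = 1.84e-06, adjusted p = 0.0235 with an estimated correlation), 0.2 in hrc1D (2 higher and 1 lower, adjusted p = 0.256), -0.74 in NIP1_depl (4 lower, adjusted p = 0.0222, adjusted p = 0.227 with an estimated correlation) and -1.63 in RLI1_depl (6 lower, adjusted p = 1.71e-05, adjusted p = 0.0358 with an estimated correlation). The calls were the same adjusted over the list alone. Under RLE the medians were 1.54, -0.07, -0.35 and -0.97 in the same order, with library totals 0.2, -0.45, 0.18 and 0.21, and in the fit of features not in RefSeq 1.22, -0.36, -0.19 and -0.65. The medians with library totals carry the shift of all features given above. Against all features the test direction was up in arf1D and down in NIP1_depl and RLI1_depl under every scaling, with camera adjusted p = 0.000153, 0.83 and 0.00674 with library totals. With an estimated correlation the arf1D test gave adjusted p = 0.00662, 0.0408 and 0.162 under these 3 alternatives and the RLI1_depl test 0.0139, 0.124 and 0.182.

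Few of the 33 lists could be tested. Through the opposite gene, 14 ribosomal protein and 6 ribosome biogenesis members passed the filter, with 3 members for chaperones and for glycolysis, 2 for initiation factors, for Gcn4 targets and for N-terminal processing and 1 for ribosome-associated quality control. Under deposited names, the lists of methionine and sulfur assimilation (8 members), iron regulon, mitochondrial ribosomal proteins, sporulation and the tricarboxylic acid cycle (6 each) could be tested. Of 50 such tests over 10 comparisons, camera called 0, with a smallest adjusted p of 0.185, and 0 with an estimated correlation. Abundant genes such as CDC19 held almost no counts under their own names, so these tests cannot tell whether the listed genes changed. In several of these tests the median, the mean and the direction differed in sign, as for mitochondrial ribosomal proteins in arf1D. The remaining lists had fewer than 5 testable members under either naming and were not tested as lists.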

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

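The tests of strand, scaling, background and regrouped libraries in this part, and the comparison by depth, were chosen after the result was seen. The tests of 1 deviating library and of ribosomes past the stop codon were written before their values were seen.

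Differences between comparisons were tested directly. MTF minus MTFi differed from EcFMT minus R42L in arf1D at 5 features, 1 higher and 4 lower, among them YER067C-A, opposite RGI1 (log2 difference -1.88, SE 0.28, adjusted p = 3.55e-08, edgeR), YER066C-A (-1.85), YKL036C, opposite UGP1 (-1.33), YPR160C-A (-1.21) and SLM6, opposite REI1 (1.05). It differed from hrc1D at 8 features, 2 higher and 6 lower, with YER067C-A at -1.95 (SE 0.31, adjusted p = 4.19e-07) and YGR160W at 0.83. It differed from NIP1_depl at 8 features, 1 higher and 7 lower, with YER066C-A at -2.09 (SE 0.34, adjusted p = 1.18e-06) and YOR121C, opposite GCY1, at -1.16. From RLI1_depl it differed at 15 features, all lower, while the 252 abundant features had a median difference of -0.41 and RLE moved the 2 contrasts in opposite directions (0.2 and -0.14 in the median of all features), so the 1-sided count carries a general shift. Among them were YDL023C, opposite GPD1, at -1.07 (SE 0.19, adjusted p = 4.35e-05), YLR198C, opposite NOP56, at -1.29 (SE 0.28, adjusted p = 0.0013) and YLR339C, opposite RPP0, at -0.74 (SE 0.16, adjusted p = 0.0013). The labels do not say that MTF and MTFi are the pair EcFMT and R42L, so these differences may compare different contrasts, and no value here settles that; scaling alone moved the MTF count from 24 to 45 under RLE scaling.

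The response to EcFMT in RLI1_depl also differed from that in other strains. The arf1D response differed from it at 4 features, with YER067C-A, opposite RGI1, at 2.43 (SE 0.44, adjusted p = 5.17e-05, edgeR) and YEL034C-A, opposite HYP2, at -0.64 (SE 0.16, adjusted p = 0.0236). The hrc1D response differed from it at 17 features, 4 higher and 13 lower beside a median of -0.31 over abundant features, with YER067C-A at 2.49 (SE 0.46, adjusted p = 8.59e-05), YLR339C, opposite RPP0, at -0.74 (SE 0.16, adjusted p = 0.00262) and YPL238C, opposite SUI3, at -0.83. The NIP1_depl response differed from it at 3 features, YER066C-A at 1.68 (SE 0.37, adjusted p = 0.00678), YGR160W at -0.94 (SE 0.23, adjusted p = 0.0239) and YPL238C at -0.82 (SE 0.21, adjusted p = 0.0471). Between arf1D and hrc1D, arf1D and NIP1_depl, and hrc1D and NIP1_depl, edgeR called 0 differences, with 59, 48 and 51 features at an unadjusted p under 0.05. DESeq2 was not run on these pairs. The 4 responses together differed at 10 features, and 27 of 100 splits of the libraries within strains gave as many, with up to 19 in another split. All 27 kept or swapped the RLI1_depl grouping, which 43 of the 100 did, and the rest gave 1 at most, so for an effect in that strain alone these splits cannot give a share under 5%. For the 5 calls of the mean response, 1 of 100 splits, the real one, gave as many, and the highest other gave 4. Under 5% of these splits reached the count, which argues against regrouping alone as its source. Chance was not excluded, since another split came close and the criterion was chosen after the result. With no filter on low counts 0 were called, and 0 without RLI1_depl.

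Counts on features opposite abundant genes were weighed against 3 explanations. Of the counts in pairs of a ribosomal protein gene and its opposite feature, 99.999% lay on the feature. Counting on the opposite strand needs this, but the value restates the pattern and is no separate support. Reads moved within overlaps are argued against by ribosomal protein genes that no listed feature opposes, which would have kept their reads and held 0.0032% of all counts. Antisense transcripts beside normally counted genes are argued against by the glycolysis list, which held 0.0023% of all counts under its own names. A candidate explanation is that the strand was inverted in counting, and apart from antisense transcripts no biological explanation was tested. While this candidate stands, counts under the name of a RefSeq gene cannot be read as translation of that gene.

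Higher counts with EcFMT opposite ribosomal protein genes in RLI1_depl were weighed next. Scaling set by low counts on RefSeq ORFs may be part of the size, since the median log2 change went from 0.46 to 0.18 in a fit of only features not in RefSeq and the 231 abundant features had a median of 0.31 under TMM, but 5 of 14 features were still called there, which argues against it as the whole cause. A single deviating library is argued against by a lowest median of 0.44 without 1 of the 4 libraries, and calls went from 10 to 5, 6, 3 and 5 without RLI1_depl_EcFMT replicate 1, RLI1_depl_EcFMT replicate 2, RLI1_depl_R42L replicate 1 and RLI1_depl_R42L replicate 2. An effect of formylation on ribosomal protein synthesis when recycling is limited, and a difference in the extent of depletion between the 2 forms, both stay open and untested, and either may explain the rest. With an estimated correlation the list test gave adjusted p = 0.122 under TMM, 0.0291 under RLE, 0.0634 with library totals and 0.0145 in the fit of features not in RefSeq.

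RLI1_depl libraries held more counts per ORF on ORFs whose convergent neighbour ends within 150 nt (833 ORFs) than on other ORFs (2486), with a ratio of 1.324 to 1.359 against 0.467 to 0.654 in the 16 other libraries. Background added alike to all ORFs, per ORF or per nt, is argued against by ORFs with a divergent neighbour within 300 nt. Their ratio to other ORFs was 0.612 at most in RLI1_depl against 0.698 at least elsewhere and 0.839 for their lengths. The convergent ratio was 1.324 in an RLI1_depl library of 123204 counts and 0.637 and 0.621 in NIP1_depl libraries of 116661 and 130424. It stayed within 1.324 to 1.359 over RLI1_depl totals of 58090 to 123204. Elsewhere it stayed within 0.467 to 0.654 over totals of 116661 to 505676. These values argue against depth as the cause. Ribosomes past the stop codon of the convergent neighbour would be read on such ORFs if the strand was inverted, and the test written for it asked whether ORFs converging on ribosomal protein genes gained most. They did not, with ratios of 0.755 to 1.153 in RLI1_depl and 1.636 to 3.27 elsewhere, over 31 such ORFs with few counts. Without the 2 highest ORFs on each side the ratios were 0.441 to 0.802 and 0.835 to 2.2, so the gap was narrow. That argues against a rise led by ribosomal protein genes and leaves open a rise at all stop codons, which could follow from a shortage of the recycling factor and was not tested.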

How the results depend on the processing

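Library totals, the fit of features not in RefSeq, the crossed block and the mean without RLI1_depl were tests chosen after the data were seen, and the cause of each change below was not tested unless stated. MTF minus MTFi gave 24 calls, 45 under RLE, 39 with library totals, 9 with no filter on low counts and 15 to 38 with 1 library left out. In arf1D 0 calls became 0 to 1 with 1 library left out and 0 with a crossed block. In hrc1D 0 became 1 with a replicate block and 0 to 3 with 1 library left out. In NIP1_depl 0 became 1 with a replicate block, 1 with a crossed block, 1 with only the 4 libraries compared and 0 to 1 with 1 library left out. Replicate numbers did not pair the libraries (correlations of -0.184 to 0.03), so the blocks are arbitrary. In RLI1_depl 48 became 9 with no filter, 27 in the fit of features not in RefSeq (42 of the 48 were such features), and 16 to 29 with 1 library left out. The mean gave 5, 8 under RLE, 0 with no filter, 12 with a replicate block, 2 in the fit of features not in RefSeq, 32 with the 16 libraries alone, 10 in DESeq2, 0 without RLI1_depl and 0 to 7 with 1 library left out. The F test gave 10, 19 under RLE, 1 with no filter, 17 with a replicate block, 23 with the 16 libraries alone, 19 in DESeq2 and 0 to 16 with 1 library left out.

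Strains in R42L: arf1D gave 517, 960 with library totals, 308 in the fit of features not in RefSeq and 387 to 507 with 1 library left out. The hrc1D strain gave 238, 138 with no filter, 154 in the fit of features not in RefSeq, 130 in DESeq2 and 137 to 235 left out. NIP1_depl gave 560, 267 in the fit of features not in RefSeq and 404 to 536 left out. RLI1_depl gave 763, 1161 with library totals, 261 in the fit of features not in RefSeq, 493 in DESeq2 and 555 to 738 left out. The fit of features not in RefSeq tests 437 features, of which 166, 262 and 271 were already called under TMM over all features in hrc1D, NIP1_depl and RLI1_depl, so most of the fall follows from testing fewer features. Lists under deposited names gave 0 of 50 tests, 0 to 1 left out. Lists through the opposite gene gave 10 of 20, 4 with an estimated correlation, 3 with a replicate block, which fits fewer comparisons, and 9 to 11 left out.

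Called values of named features, or values called under an alternative, reversed only in the strain comparisons. YPL238C in NIP1_depl (-0.3) became 0.09 under RLE, 0.09 in the fit of features not in RefSeq, 0.09 in DESeq2 and 0.62 with library totals. YNL103W-A in RLI1_depl (-0.2) became 0.47 under RLE, 0.38 with EcFMT libraries, 0.68 in the fit of features not in RefSeq and 1.65 with library totals. Library totals moved all features by -2.01 in arf1D, -0.65 in hrc1D, 0.88 in NIP1_depl and 1.81 in RLI1_depl, so the reversals they gave carry that shift. There, arf1D reversed for YPL238C (-0.63), YPR050C (-1.14) and YLR217W (-1.07), hrc1D for YPL238C (-0.12), YGL214W (-0.03) and YPR050C (-0.2), NIP1_depl for YPL250W-A (0.05), YPL197C (0.09), YLR062C (0.19), YNL174W (0.02), YLR198C (0.34), YNL103W-A (0.69) and YPR050C (0.46), and RLI1_depl for YPL238C (0.13), YGL214W (0.23), YMR290W-A (0.1), YNL174W (0.33), SLM6 (0.05), YPR050C (0.88) and YLR217W (0.9). Of 3976 values of named features under an alternative, 340 lost the call, 28 gained it and 28 reversed as above. The other 3580 kept their side of the threshold, 127 of them uncalled values that turned sign, 40 in MTF minus MTFi. At totals down to 58090 counts, features with few counts were tested weakly, since 20 to 28% of simulated 2-fold changes were recovered over all features.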

Other observations

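These values were noticed after the data were seen. Between replicates, counts differed by a chi-square per degree of freedom of 8.59 in MTF and 2.88 in hrc1D with R42L, against 1.46 to 1.76 in the other 8 groups. YIL082W-A and YGR109W-B, a pair of Ty3 copies, held 11 and 13 counts together in arf1D with R42L and 68 and 75 in hrc1D with R42L. The 10 features with most counts took 65.4% of MTFi libraries and 32.4% of RLI1_depl libraries with R42L.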
